A study of Homo sapiens with 6 samples.

How the data were processed

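Small RNA was sequenced from K562 cells, a human erythroleukaemia line, in an azacitidine-sensitive form and in a form made resistant by growth in rising azacitidine concentrations over several months. Azacitidine is a cytidine analogue that is built into nucleic acids and lowers DNA methylation by trapping DNA methyltransferases. Each form had 3 libraries that the labels call biological replicates, which gave 6 libraries in all. Per the labels' protocols, RNA was isolated with TriPure reagent and treated with DNase, libraries were made with a NEBNext small RNA kit, and sequencing was on an Illumina NovaSeq instrument. Whether azacitidine was present in the medium at harvest is not stated in the labels, and the letters NT that end all 6 library names are not explained there. So a lasting change and a direct effect of the drug are not separated by the comparison. The labels name replicates but no separate selections of resistant cells, so the p-values cover the spread between libraries. Changes that arose in the resistant form without bearing on resistance cannot be told apart from those tied to it.

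The authors deposited a table of read counts per mature miRNA, with 2656 miRNAs and 1 column per library. The values are whole numbers with column totals that differ between libraries, and no normalization was found in them. The genome build is GRCh38 per the submitters' processing notes. The aligner, the counting program, the miRBase release and any filter on reads are not given in the sources used here. How reads that match several near-identical miRNAs were counted is therefore unknown, and values of the let-7 family members, of miR-548 family members and of miR-3689 family members are uncertain for that reason. The kit ligates adapters to RNA ends and the counts carry no molecular identifiers, so ligation and amplification preferences of single miRNAs enter the counts, and intervals and floors from counts cover counting error only.

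Library totals were 12563945, 10197963 and 5660055 counts for sensitive replicates 1 to 3 and 8305961, 10644739 and 3291500 counts for resistant replicates 1 to 3. Counts were found for 1120 to 1383 miRNAs per library, and 1734 of the 2656 miRNAs had a count in at least 1 library. Replicates of a group were compared with a chi-square test of their counts. Chi-square per degree of freedom ran from 152 to 4776, so no pair agreed within sampling noise, as 2 deposits of 1 library would. This check does not show that the replicates are independent cultures, and the 6 libraries were counted as labelled.

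Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total count 15, by group), which left 768 miRNAs. Trimmed mean of M values (TMM) factors scaled the libraries. Resistant and sensitive libraries were compared with edgeR's quasi-likelihood F test without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are counts relative to library size scaled by the TMM factors. All log2 fold changes are resistant over sensitive. Their standard errors (SE) are approximate, computed as the absolute log2 fold change divided by the square root of the F statistic. For a miRNA without counts in a group, the fold change is given as a bound from a floor of 3 counts over the group. Shares of a library's counts have exact 95% binomial intervals. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p under 0.1, so none was run.

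Gene lists were fixed before the data were examined. They hold the miRNAs of exon 1 of H19, the let-7 family, the miR-17/92 clusters and their paralogues, erythroid, myeloid, and stem and progenitor miRNAs, miR-221/222, the miR-183/96/182 cluster, the miR-29 and miR-148/152 families, miRNAs reported as silenced by DNA methylation in cancer, p53-responsive miRNAs, a part of the imprinted 14q32 cluster, the 19q13 clusters, the Xq27.3 cluster, miRNAs of non-blood tissues, and annotations that resemble fragments of other RNAs, used as a sign of RNA quality. The 12 lists with at least 3 tested members were tested with fry of limma 3.58.1, which asks whether the members move on balance in 1 direction and compares the list with no other miRNAs. Camera, which does compare a list with the other miRNAs, was run with a preset correlation of 0.01 and with an estimated correlation. Some members belong to several lists, among them 16 of the methylation-silenced, 9 of the p53-responsive and 13 of the non-blood list.

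miRNAs were named by a rule that was also fixed before the data were examined. It takes miR-675-5p and miR-675-3p, the 3 most abundant miRNAs, up to 10 rises and 10 falls with the largest log2 fold change among called miRNAs with a mean of at least 10 CPM and no overlap between the groups, and from each list the most abundant member and the 2 members with the lowest adjusted p. Of the rises and of the falls, 9 each met the rule. Other miRNAs that are named were chosen after their values were seen. Hairpins were placed on GRCh38 with the GENCODE 29 annotation by gene name. GC content was taken from the annotated hairpin transcript, because mature sequences were not used here. It covers the side of the hairpin, cut at its middle, that holds the miRNA. Where the name of a miRNA gives no arm, it covers the whole hairpin. For a miRNA with several hairpins the values were averaged.

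The test procedure was tried on simulated counts with known changes. In counts drawn from the means, library sizes and spread of all 6 libraries, with 200 of 768 miRNAs changed, it recovered 7.46% of 2-fold, 44.8% of 4-fold and 98.5% of 8-fold changes, and 2 of 102 calls were false. In the design without resistant replicate 3, with 822 miRNAs, it recovered 49.3% of 2-fold, 95.5% of 4-fold and 100% of 8-fold changes, and 6 of 169 calls were false. A simulated list raised 4-fold had a fry adjusted p of 0.00618, and 0 of the other lists passed. The simulated miRNAs varied independently of each other, with the same spread in every library. Deviations that many miRNAs share in a library were therefore absent, and these rates may not hold for the real counts.

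Alternatives planned before the data were examined were relative log expression (RLE) size factors, library totals without TMM, no filter, a minimum mean of 10 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. Limma-voom with library quality weights, a correction for GC content by a loess curve per library, and that correction without resistant replicate 3 were added after resistant replicate 3 was seen to stand apart.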

Results

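The miRNA content of azacitidine-sensitive and azacitidine-resistant K562 cells was compared by small RNA sequencing of 3 biological replicates each. The series concerns H19, an imprinted long non-coding RNA, in the resistant cells, and the counts address which mature miRNAs differ between both forms of the line, those made from H19 included. Library totals ranged from 3291500 counts in resistant replicate 3 to 12563945 counts in sensitive replicate 1, and 768 miRNAs had enough counts to be tested.

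Both mature products of the H19 hairpin were far more abundant in resistant cells. miR-675-5p was 43.2-fold higher, at 5.28 ± 0.577 CPM in sensitive and 229 ± 116 CPM in resistant cells (SD, n = 3 each; log2 fold change 5.43, SE 0.55, edgeR adjusted p = 0.00219). miR-675-3p was 36.6-fold higher, at 10.6 ± 1.69 CPM in sensitive and 388 ± 149 CPM in resistant cells (SD, n = 3 each; log2 fold change 5.19, SE 0.50, edgeR adjusted p = 0.00219). Their hairpin, MIR675, lies on the minus strand of chromosome 11 at 1996759 to 1996831 (GRCh38), inside exon 1 of H19, which spans 1996518 to 1997217 in the shortest annotated form of that exon. Without resistant replicate 3 the increases were 31.6-fold for miR-675-5p and 29.4-fold for miR-675-3p, each with an edgeR adjusted p of 1.08e-07. With all libraries and a correction for GC content chosen after seeing the data, their log2 fold changes were 4.28 and 4.11. Without sensitive replicate 2, miR-675-5p missed the threshold (log2 fold change 5.68, edgeR adjusted p = 0.0548, the highest over its alternatives, of which the lowest was 2.50e-20 with DESeq2).

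Across all tested miRNAs, 32 passed the threshold, 16 higher and 16 lower in resistant cells. let-7 family members, miR-135a-3p, miR-196a-5p and miR-200c-3p were among the miRNAs that rose, and miR-181a-3p, miR-99a-5p, miR-125b-5p and both arms of miR-625 were among those that fell. When libraries were scaled by their totals alone, 27 were higher and 16 lower, so that 62.8% of the calls were higher against 50% with TMM factors. With DESeq2, 98 were higher and 51 lower. An unadjusted p under 0.05 was found for 205 of the 768 miRNAs with edgeR, and the CPM of the groups did not overlap for 321 (41.8%, where chance gives 10% on average over the possible splits). The miRNAs of a library vary together, so this share alone cannot tell a difference between the groups from chance.

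The number of calls depended on resistant replicate 3. Resistant replicate 3 correlated with resistant replicates 1 and 2 at r = 0.875 and 0.864 across miRNAs (Pearson, log2 CPM), while these correlated with each other at 0.995 and the sensitive replicates with each other at 0.978 to 0.992. miR-92a-3p made up 58.6% of its counts (exact 95% interval 58.6% to 58.7%), against 20.2% and 17.5% in resistant replicates 1 and 2, and fragment-like annotations made up 4.93% against 0.992% and 1.02%. Without this library, 231 of 822 tested miRNAs passed, 113 higher and 118 lower, and these included all 32 calls made with the 6 libraries. Of the 231, 218 were also tested with all libraries, and 213 of those had the same direction there. The fits share all libraries but resistant replicate 3, so this overlap and shared direction are not independent evidence. Leaving out any of the other libraries gave 4 to 26 calls. The log2 deviation of resistant replicate 3 from resistant replicates 1 and 2 rose with the GC content of the hairpin side that holds the miRNA across 757 miRNAs (Spearman's rho 0.596, miRNAs not being independent replicates). Across miRNAs, the log2 fold changes between the groups rose with GC content too. Spearman's rho was 0.507 with all 6 libraries and 0.339 without resistant replicate 3.

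**Figure D1:**
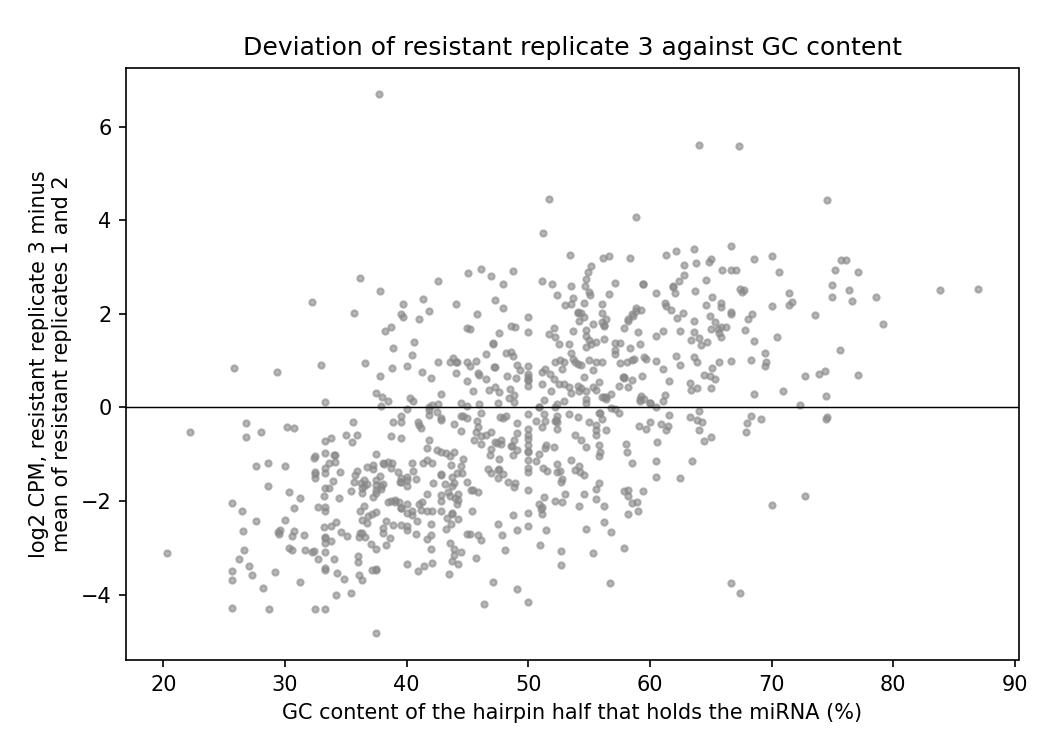
Deviation of resistant replicate 3 from the mean of resistant replicates 1 and 2 (log2 CPM) against the GC content (%) of the hairpin side that holds the miRNA (the whole hairpin where the name gives no arm), 1 point per tested miRNA. The median deviation was -1.72 for miRNAs at or below 43.4% GC and 1.04 for those at or above 54.6%.

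Among called miRNAs with a mean of at least 10 CPM and no overlap between groups, those that rose most besides miR-675 were miR-135a-3p and let-7b-5p. miR-135a-3p, from a hairpin on chromosome 3, went from 7.20 ± 1.52 to 162 ± 134 CPM, a 22.5-fold increase (SD, n = 3 each; log2 fold change 4.49, SE 0.70, edgeR adjusted p = 0.0154). It was 12.4-fold without resistant replicate 3. miR-196a-5p, made from hairpins beside HOXB7 and HOXC6, went from 87.8 ± 15.5 to 515 ± 129 CPM (5.87-fold, log2 fold change 2.55, SE 0.41, edgeR adjusted p = 0.0154). miR-200c-3p, a miRNA of epithelial cells whose promoter is methylated in many mesenchymal cells, went from 91.5 ± 11.2 to 351 ± 76.2 CPM (3.83-fold, log2 fold change 1.94, SE 0.38, edgeR adjusted p = 0.0355). Its family did not move together. miR-200a-3p, miR-200b-3p and miR-429 had negative log2 fold changes (-1.53, -0.75 and -1.06), miR-141-3p had 0.63, and none of these passed. Without resistant replicate 3, miR-200a-3p fell (-1.14, edgeR adjusted p = 0.0139) and miR-141-3p rose (1.15, edgeR adjusted p = 0.0163). miR-196a-5p and miR-200c-3p passed in 2 of the 6 fits that each left out 1 library, and miR-135a-3p in 3. With the replicate number as a block, miR-200c-3p did not pass.

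The let-7 family, whose members repress RAS, MYC and HMGA2 transcripts and increase as cells differentiate, was higher as a group. Of its 9 tested members 4 rose, 0 fell and 5 did not pass the test over all miRNAs, and adjusted over the list alone 7 rose. let-7b-5p went from 7.88 ± 1.43 to 178 ± 155 CPM (22.4-fold, log2 fold change 4.49, SE 0.71, edgeR adjusted p = 0.0154) and was 11.5-fold higher without resistant replicate 3. let-7a-5p, the most abundant member, went from 1262 ± 112 to 7258 ± 3027 CPM (5.75-fold, log2 fold change 2.52, SE 0.43, edgeR adjusted p = 0.0198). let-7c-5p (6.65-fold) and let-7d-5p (4.54-fold) were the other members that rose (3.999-fold and 3.37-fold without resistant replicate 3). With RLE factors neither passed (edgeR adjusted p = 0.0628 for each). Over the 6 fits that each left out 1 library, let-7b-5p passed in 3, let-7a-5p and let-7c-5p in 2 and let-7d-5p in 1. The family made up 0.337 ± 0.0288% of the counts in sensitive and 1.20 ± 0.0499% in resistant libraries (SD, n = 3 each). All 9 members had positive log2 fold changes with TMM factors, RLE factors and library totals. With TMM factors their median was 1.16 (fry adjusted p = 0.0387, camera adjusted p = 4.78e-05 with a preset and 0.176 with an estimated correlation). Without resistant replicate 3, 8 of the 9 rose (median 1.30, fry adjusted p = 0.000413, adjusted p = 0.0784 with an estimated correlation in camera). With all libraries the list also passed under RLE factors (fry adjusted p = 0.0284), library totals (fry adjusted p = 3.32e-05) and no filter (fry adjusted p = 0.0243). A minimum mean of 10 CPM (fry adjusted p = 0.0380), limma-voom (fry adjusted p = 0.00747) and quality weights chosen after the result was seen (fry adjusted p = 0.000345) kept the call. Leaving out any other library ended the list's call (medians 1.31 to 1.75, fry adjusted p = 0.105 to 0.138), as did a GC correction chosen after the result was seen (median 1.49, fry adjusted p = 0.0511). The replicate number as a block also ended it (median 1.15, fry adjusted p = 0.0666), with 1 member higher. let-7 members that differ by single bases cannot be separated with certainty here.

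**Figure D2:**
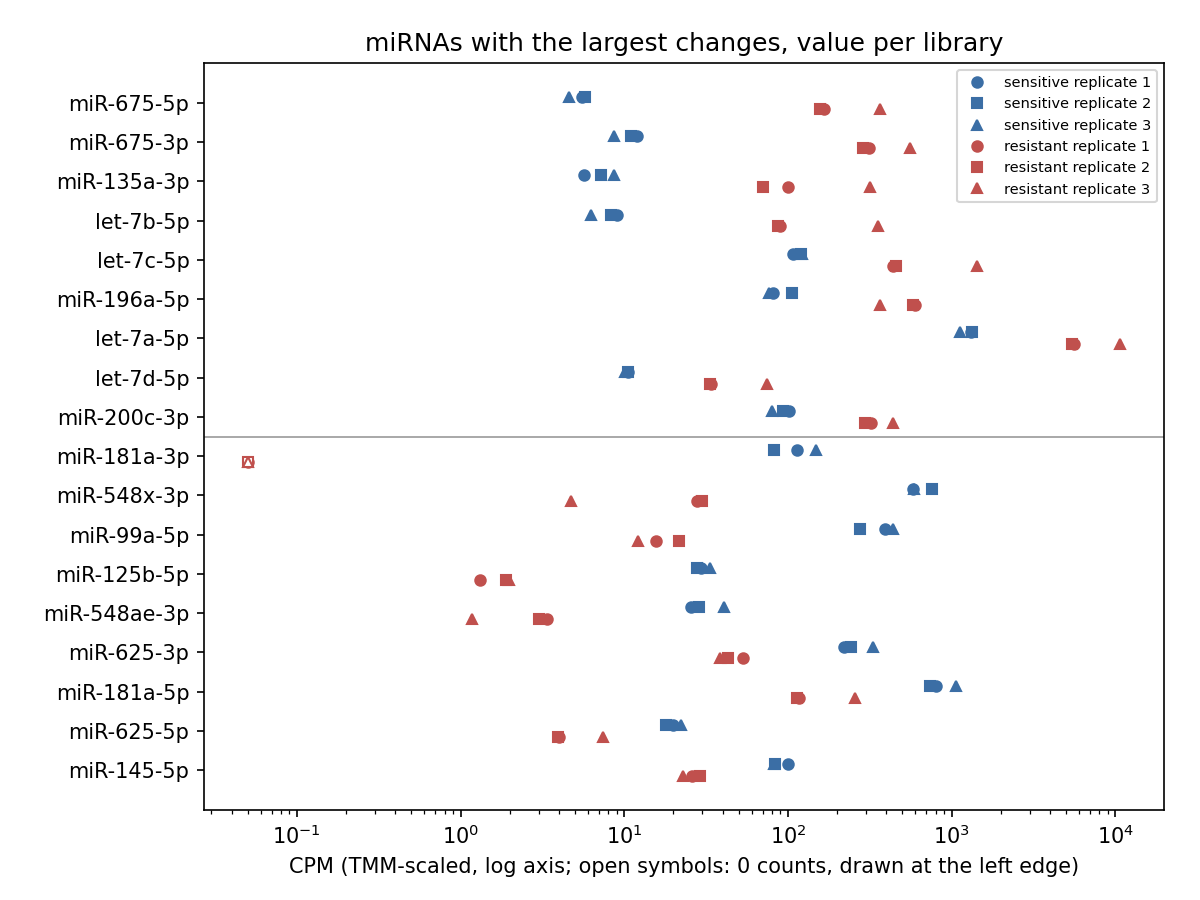
Normalised abundance (CPM scaled by TMM factors, log axis) of the miRNAs with the largest called changes, 1 symbol per library, sensitive in blue and resistant in red, miRNAs that rose above the line and miRNAs that fell below it. Each plotted miRNA has groups that do not overlap, and miR-181a-3p has 0 counts in the 3 resistant libraries (open symbols, drawn at the left edge).

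miR-181a-3p, at 115 ± 32.7 CPM in sensitive cells (SD, n = 3; 1372, 808 and 799 counts), had 0 counts in each of the 3 resistant libraries. That was at least 981-fold lower with a floor of 3 counts over the resistant group (edgeR adjusted p = 0.00219). Its hairpin MIR181A1 lies at 198859044 to 198859153 on the minus strand of chromosome 1, within the host transcript MIR181A1HG. miR-181b-3p, made from the neighbouring hairpin and named after its values were seen, also had 0 counts in the resistant libraries against 6.50 ± 3.51 CPM in sensitive cells, at least 55.5-fold lower (edgeR adjusted p = 0.0154). miR-181a-5p, which a hairpin on chromosome 9 also makes, fell 5.34-fold from 866 ± 170 to 163 ± 81.8 CPM (log2 fold change -2.42, SE 0.48, edgeR adjusted p = 0.0355).

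miR-99a-5p and miR-125b-5p, miRNAs of haematopoietic stem and progenitor cells, fell 22.3-fold and 17.7-fold. miR-99a-5p went from 370 ± 83.5 to 16.5 ± 4.84 CPM (SD, n = 3 each; log2 fold change -4.48, SE 0.47, edgeR adjusted p = 0.00219) and miR-125b-5p from 30.3 ± 2.89 to 1.72 ± 0.350 CPM (log2 fold change -4.14, SE 0.44, edgeR adjusted p = 0.00219). MIR99A lies at 16539089 to 16539169 on the plus strand of chromosome 21 in the host gene MIR99AHG, which also holds MIRLET7C and 1 of the 2 hairpins of miR-125b-5p. With miR-181a-3p, these were the miRNAs outside miR-675 and named by the rule that passed in each of the 6 fits that left out 1 library.

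Both arms of miR-625, whose hairpin lies in FUT8, fell: miR-625-3p by 5.88-fold from 264 ± 59.2 to 44.8 ± 7.32 CPM (edgeR adjusted p = 0.0154) and miR-625-5p to 5.12 ± 2.03 CPM (edgeR adjusted p = 0.0482), which was 4.85-fold lower without resistant replicate 3. miR-548x-3p fell 30.6-fold from 644 ± 100 CPM in sensitive cells (log2 fold change -4.93, SE 0.73, edgeR adjusted p = 0.0154). miR-548ae-3p fell from 31.8 ± 8.04 to 2.52 ± 1.17 CPM (edgeR adjusted p = 0.0143). These members of the miR-548 family share sequence with many copies, so which copy the reads came from is uncertain. miR-145-5p, which p53 induces, fell 3.40-fold from 88.4 ± 9.94 to 26.0 ± 3.17 CPM (edgeR adjusted p = 0.0467). It did not pass with RLE factors (edgeR adjusted p = 0.0571) or library totals (edgeR adjusted p = 0.0794), nor with a minimum mean of 10 CPM or the replicate number as a block. With RLE factors miR-181a-5p and miR-625-5p did not pass either (edgeR adjusted p = 0.0657 and 0.0845). Over the 6 fits that each left out 1 library, miR-548x-3p and miR-548ae-3p passed in 2, and miR-145-5p, miR-181a-5p and both arms of miR-625 in 1.

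Among the most abundant miRNAs, no change was called with all 6 libraries. miR-21-5p, an abundant miRNA of many cancers, held 17.4 ± 1.55% of the counts in sensitive libraries and 8.67%, 8.31% and 0.635% in resistant replicates 1 to 3 (exact 95% intervals 8.65% to 8.69%, 8.29% to 8.33% and 0.626% to 0.644%). Its log2 fold change was -1.88 (edgeR adjusted p = 0.166), and without resistant replicate 3 it passed at -1.33 (edgeR adjusted p = 8.43e-05). miR-92a-3p (log2 fold change 1.41, edgeR adjusted p = 0.225) and miR-20a-5p (log2 fold change -0.59, edgeR adjusted p = 0.551), both of the miR-17/92 clusters, did not pass in either fit. Without resistant replicate 3 their log2 fold changes were 0.27 and -0.09 (edgeR adjusted p = 0.294 and 0.774).

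The listed members of the imprinted 14q32 cluster, which is expressed from the maternal chromosome and includes miR-381-3p, made up 22.6 ± 3.30% of the counts in sensitive libraries and 14.1%, 16.3% and 6.18% in resistant replicates 1 to 3 (exact 95% intervals 14.04% to 14.08%, 16.30% to 16.35% and 6.15% to 6.20%). Of the 66 tested members of the list, 56 had a negative log2 fold change (median -1.02). The list leaves out other tested arms of the cluster's hairpins, such as miR-381-5p, miR-410-5p and miR-889-5p. Counts of members, medians and shares given here are therefore not those of the whole cluster. Of the 66 members, 0 passed over all miRNAs or adjusted over the list alone (fry adjusted p = 0.0713; camera adjusted p = 1.17e-05 with a preset and 0.503 with an estimated correlation). With all libraries the list passed under RLE factors (fry adjusted p = 0.0284), a minimum mean of 10 CPM (fry adjusted p = 0.0380) and a GC correction chosen after the result was seen (fry adjusted p = 0.0313), with 0 members called in each. It also passed with library quality weights, likewise chosen after the result was seen (fry adjusted p = 0.00715), with 42 members lower and 2 higher. DESeq2 called 10 members lower and 0 higher. Without a filter 9 were lower and 0 higher, and the list did not pass (fry adjusted p = 0.150). With resistant replicate 3 left out, 32 of 67 members fell and 0 rose. Adjusted over the list alone, 36 then fell and 1 rose (median -0.64, fry adjusted p = 0.00444, adjusted p = 0.0784 with an estimated correlation in camera). miR-381-3p then fell 2.65-fold (edgeR adjusted p = 0.00238), miR-758-3p 2.14-fold (edgeR adjusted p = 0.00199) and miR-329-3p 1.98-fold (edgeR adjusted p = 0.00301). The listed members had a median GC content of 43.5% against 48.8% over all tested, and log2 fold changes without resistant replicate 3 rose with GC content across miRNAs (Spearman's rho 0.339, miRNAs not being independent). With a correction for GC content in the same 5 libraries, chosen after seeing the data, 27 members fell and 0 rose (median -0.56).

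Of 10 tested stem and progenitor miRNAs, 2 fell, miR-99a-5p and miR-125b-5p, and 0 rose, over all miRNAs and adjusted over the list alone (median -0.66, fry adjusted p = 0.0541, adjusted p = 0.387 with an estimated correlation in camera). With all libraries the list passed under RLE factors (fry adjusted p = 0.0284), a minimum mean of 10 CPM (fry adjusted p = 0.0380), limma-voom (fry adjusted p = 0.0324) and the GC correction (fry adjusted p = 0.0313). It also passed with library quality weights (fry adjusted p = 0.0037), with 6 members lower and 2 higher. With resistant replicate 3 left out, 4 fell and 2 rose, and adjusted over the list alone 5 fell and 2 rose (fry adjusted p = 0.0157, adjusted p = 0.263 with an estimated correlation in camera). The members that rose were miR-10b-5p and miR-196b-5p, from the HOXD and HOXA loci, and miR-126-3p, an endothelial and stem cell miRNA, fell 1.76-fold. All 8 tested myeloid miRNAs had negative log2 fold changes (median -0.97) and 0 passed over all miRNAs or adjusted over the list alone (fry adjusted p = 0.222). In the fit without resistant replicate 3, miR-223-3p, the granulocyte miRNA, fell 1.99-fold. miR-146a-5p and miR-146b-5p, which dampen NF-kappaB signalling, fell 1.77-fold and 1.76-fold. These were the 3 members that passed, also adjusted over the list alone (fry adjusted p = 0.0157, adjusted p = 0.281 with an estimated correlation in camera).

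The cluster of miR-183, miR-96 and miR-182 on chromosome 7 had 0 of 6 members called over all miRNAs and 1 higher adjusted over the list alone, miR-182-3p (median 1.12, fry adjusted p = 0.0713). With all libraries the list passed under RLE factors (fry adjusted p = 0.0284) and a minimum mean of 10 CPM (fry adjusted p = 0.0380). It also passed with library quality weights, chosen after the result was seen (fry adjusted p = 0.0133), with 5 members higher and 0 lower. When resistant replicate 3 was left out, 5 of the 6 rose, also adjusted over the list alone, with miR-182-3p 2.52-fold and miR-183-3p 2.29-fold higher (fry adjusted p = 0.0279, adjusted p = 0.263 with an estimated correlation in camera). For the miR-17/92 clusters, which promote proliferation, 0 of 19 members passed over all miRNAs or adjusted over the list alone. Their median log2 fold change of -0.20 had the opposite sign to the mean of 0.41 and to the fry direction (fry adjusted p = 0.476), with a median of 0.08 when libraries were scaled by totals. In the fit without resistant replicate 3, 6 members rose, also adjusted over the list alone (median 0.27, fry adjusted p = 0.00436, adjusted p = 0.263 with an estimated correlation in camera). Among them were miR-25-5p (3.01-fold, against 7.68-fold with all libraries, edgeR adjusted p = 0.0853) and miR-92a-1-5p (2.89-fold, against 9.01-fold, edgeR adjusted p = 0.0981). The others were miR-25-3p, miR-93-5p, miR-93-3p and miR-106b-3p, which like miR-25-5p belong to the paralogues in the list. From miR-17/92 itself only miR-92a-1-5p rose. In that fit miR-17-5p, miR-18a-5p, miR-19a-3p, miR-19b-3p, miR-20a-5p and miR-92a-3p did not pass (log2 fold changes -0.24 to 0.27). Of 6 erythroid miRNAs 0 passed over all miRNAs or adjusted over the list alone (fry adjusted p = 0.476). In the fit without resistant replicate 3, miR-486-5p and miR-486-3p, which accompany erythroid maturation, rose 2.07-fold and 1.80-fold, also adjusted over the list alone (fry adjusted p = 0.259). With all libraries they were 5.05-fold and 3.25-fold higher (edgeR adjusted p = 0.130 and 0.135). With a correction for GC content, chosen after seeing the data, and resistant replicate 3 left out, 0 of the 6 erythroid members passed (median 0.18, fry adjusted p = 0.656). With all libraries 3 members were positive and 3 negative, among the latter miR-451a (log2 fold change -0.94, edgeR adjusted p = 0.296).

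**Figure D3:**
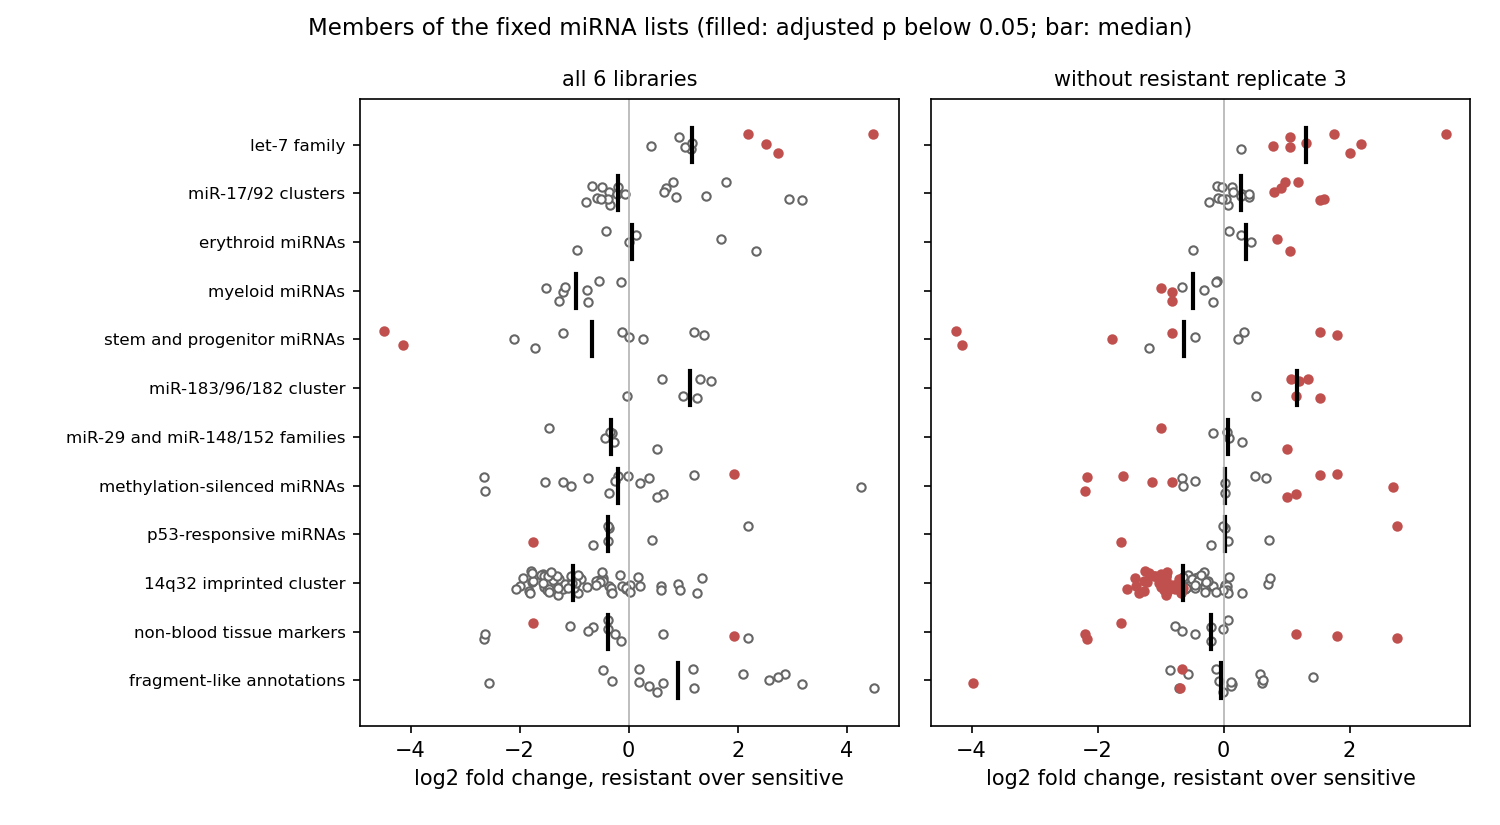
log2 fold changes (resistant over sensitive) of the tested members of the 12 tested lists with all 6 libraries (left) and without resistant replicate 3 (right), each circle 1 miRNA, filled where its edgeR adjusted p is below 0.05, with a bar at the list's median. Filled members of the let-7 family lie to the right in both panels, 4 in the left and 8 in the right, and filled members of the 14q32 cluster appear in the right panel only, where 32 fell.

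miRNAs reported as silenced by DNA methylation in cancers did not move together. Of 17 tested members 1 rose, miR-200c-3p, and 0 fell, and adjusted over the list alone 2 rose and 2 fell (median -0.19, fry adjusted p = 0.476). When resistant replicate 3 was left out, 5 of 18 rose and 5 fell, and adjusted over the list alone 6 rose and 6 fell (fry adjusted p = 0.866). miR-193a-5p, miR-148a-3p and miR-200c-3p were among those that rose, and miR-9-5p and miR-9-3p fell 4.50-fold and 4.60-fold. The miR-29 family and the miR-148 and miR-152 family, which target DNA methyltransferase transcripts, had 0 of 6 members called over all miRNAs or adjusted over the list alone (median -0.33, fry adjusted p = 0.476). With resistant replicate 3 left out, miR-148a-3p rose 2.01-fold while miR-29a-3p fell 1.99-fold, also adjusted over the list alone (fry adjusted p = 0.762). Of 7 p53-responsive miRNAs 1 fell, miR-145-5p, over all miRNAs and adjusted over the list alone (fry adjusted p = 0.518). In the fit without resistant replicate 3, miR-143-3p, from the same host transcript as miR-145-5p, rose 6.72-fold and miR-145-5p fell 3.08-fold among 8 tested members, also adjusted over the list alone (fry adjusted p = 0.428). In resistant replicate 3 miR-143-3p had 35 counts.

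miR-221-3p and miR-222-3p, which repress KIT and the cell cycle inhibitor CDKN1B, were 0 of 2 called over all miRNAs, and adjusted over the list alone both fell, by 3.11-fold and 2.85-fold. When resistant replicate 3 was left out, both fell over all miRNAs and adjusted over the list alone, by 3.33-fold and 3.48-fold. Of the 19q13 clusters, which are active in placenta and embryonic stem cells, 2 of 53 members had enough counts to be tested. miR-372-3p fell from 3.86 ± 0.939 to 0.236 ± 0.211 CPM (SD, n = 3 each; edgeR adjusted p = 0.0198), on 4, 4 and 0 counts in the resistant libraries, and passed in 1 of the 6 fits that each left out 1 library. miR-373-3p had a log2 fold change of -1.93 (edgeR adjusted p = 0.130). Adjusted over the list alone, both fell. The 1 tested member of the Xq27.3 cluster, miR-514a-3p, had a log2 fold change of -1.85 (edgeR adjusted p = 0.134) and fell adjusted over the list alone, where it was the only test.

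Markers of tissues other than blood held 0.774 ± 0.255% of the counts in sensitive and 0.334 ± 0.194% in resistant libraries (SD, n = 3 each). The most abundant, miR-9-5p, had 4858 ± 2142 CPM in sensitive and 767 ± 477 CPM in resistant libraries (edgeR adjusted p = 0.0727). Of 13 tested members 1 rose (miR-200c-3p) and 1 fell (miR-145-5p), and adjusted over the list alone 1 rose and 3 fell (fry adjusted p = 0.460). With resistant replicate 3 left out, 3 rose and 3 fell, also adjusted over the list alone (fry adjusted p = 0.762). Fragment-like annotations had 0 of 16 members called over all miRNAs or adjusted over the list alone (median 0.90, fry adjusted p = 0.521). When resistant replicate 3 was left out, 0 of 17 rose and 4 fell, also adjusted over the list alone (median -0.07, fry adjusted p = 0.0588). miR-4485-3p, whose sequence matches mitochondrial ribosomal RNA, was then 15.7-fold lower, against 5.92-fold with all libraries (edgeR adjusted p = 0.130). miR-1260b, which resembles a transfer RNA fragment, was 1.58-fold lower (edgeR adjusted p = 0.0189) against 2.28-fold higher with all libraries (edgeR adjusted p = 0.398).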

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

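The GC corrections and library quality weights were chosen after the result was seen. miR-675-3p passed under every alternative run and miR-675-5p under all but the fit without sensitive replicate 2, where its log2 fold change was 5.68 (range 4.98 to 5.91 over the fits that left out 1 library). Leaving out each library in turn gave 4 to 231 changed miRNAs, 1 to 113 higher, 3 to 118 lower and 0 to 6 lists past the threshold, the highest of each without resistant replicate 3. RLE factors, which moved the median of all tested miRNAs by 0.10, gave 21 changed, 9 higher and 4 lists, and library totals, which moved it by 0.20, gave 27 higher. No filter gave 162 changed, 115 higher and 47 lower among 1734 tested, and a minimum mean of 10 CPM gave 14, 8 and 6 among 471 tested, with 4 lists. DESeq2 gave 149 changed, 98 higher and 51 lower, with 18 adjusted p-values not given, and limma-voom gave 2 lists. Quality weights gave 323 changed, 148 higher, 175 lower and 5 lists, with a weight of 0.0621 for resistant replicate 3 and 0.709 to 2.96 for the others. GC correction gave 54 changed, 31 higher and 2 lists, and without resistant replicate 3 it gave 210 changed, 94 higher, 116 lower and 7 lists. Camera called 2 lists with a preset and 0 with an estimated correlation. miR-1260b reversed to -0.66 without resistant replicate 3, to -0.91 with GC correction in addition and to -0.63 with quality weights, and it ranged from -0.66 to 1.97 over the fits that left out 1 library. For the named miRNAs outside miR-675, 552 of 745 values over the alternatives kept direction and side of the threshold, 110 newly passed, 78 no longer passed, 2 not called in either fit changed sign and 3 were the reversals of miR-1260b. Beyond the fewer libraries or the other number of miRNAs tested that some alternatives bring, the cause of these moves was not tested.

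With the replicate number as a block, 23 miRNAs changed, 8 higher and 15 lower, and 0 lists passed (let-7 median 1.15, fry adjusted p = 0.0666). The fit without pairing was planned before the data were examined, with the block as an alternative. Deviations from the group means correlated between libraries of the same number at -0.06, 0.26 and 0.13. These few values, in part from resistant replicate 3, cannot show whether libraries of the same number are paired.

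The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 32 changed, 16 higher, 16 lower and 1 list, and the highest of the other splits gave 0 of each, so 1 of the 10 splits reached each count. With all 6 libraries, simulated 2-fold changes were recovered in 7.46% of cases. Changes of that size were thus mostly not detectable at this spread, in simulated counts without deviations shared across miRNAs.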

Other observations

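The test of a swap or mixture for resistant replicate 3 was chosen after the result was seen. The miRNAs of this and the next paragraph were chosen after their values were seen. Without resistant replicate 3, miR-10b-5p (log2 fold change 1.80, edgeR adjusted p = 0.000271), from HOXD3, miR-196b-5p (1.53, edgeR adjusted p = 0.00669), from HOXA9, and miR-196a-3p (2.20, edgeR adjusted p = 0.00013), from HOXC6, rose. With all 6 libraries these had 1.39, 1.20 and 1.74 and did not pass (edgeR adjusted p = 0.148, 0.205 and 0.134). Of the other tested miRNAs at HOX loci, in the fit without resistant replicate 3, miR-196a-5p (2.80, edgeR adjusted p = 2.94e-06), miR-196a-1-3p (3.12, edgeR adjusted p = 0.0073) and miR-615-3p (1.07, edgeR adjusted p = 0.0363) passed. miR-10a-5p (0.32, edgeR adjusted p = 0.236), miR-10a-3p (0.28, edgeR adjusted p = 0.373), miR-615-5p (0.75, edgeR adjusted p = 0.332) and miR-7704 (-0.56, edgeR adjusted p = 0.545) did not, and with all 6 libraries only miR-196a-5p passed.

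miR-202-5p had 133, 141 and 44 counts in sensitive and 1558, 2224 and 49 counts in resistant replicates 1 to 3. Its log2 fold change was 3.36 with all 6 libraries (edgeR adjusted p = 0.0566) and 3.90 without resistant replicate 3 (edgeR adjusted p = 1.58e-06). let-7b-3p, the other arm of the let-7b hairpin on chromosome 22, had 0 counts in each sensitive library and 8, 11 and 5 counts in the resistant libraries. let-7a-3p, made in part from the neighbouring hairpin, had 1.45 with all 6 libraries (edgeR adjusted p = 0.190) and 1.96 without resistant replicate 3 (edgeR adjusted p = 5.26e-05). Its 37.7 CPM in resistant replicate 3 lay below the 53.4 to 61.8 CPM of the sensitive libraries.

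Resistant replicate 3 differed from the other resistant libraries. Values argued against 3 explanations: without miR-92a-3p, the SD of its deviation was still 5.31 times that between resistant replicates 1 and 2. Resistant replicate 1 thinned to its depth still correlated with resistant replicate 2 at 0.988, against 0.866 for resistant replicate 3. A mixture with sensitive cells would raise miR-181a-3p, miR-548x-3p and miR-99a-5p, each abundant in sensitive cells and at least 10-fold lower in resistant replicates 1 and 2. With the GC trend of the library taken out, their levels allowed for at most 2.11% of sensitive cells (miR-181a-3p, with its 0 counts set to a floor of 3). A loss of miRNAs with low GC content may account for part of the pattern (rho 0.596, against -0.245 to 0.236 in like comparisons among the other libraries, with 34.3% of the variance on a loess curve), and what led to that loss, and any biological difference of this culture, was not tested.

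miR-99a-5p, miR-125b-5p and let-7c-5p share the host gene MIR99AHG on chromosome 21, yet the first and second of these fell while let-7c-5p rose. Reads of let-7c-5p that come from other let-7 members may explain its rise, but the other arm, let-7c-3p, had 10 counts over the 6 libraries, too few to test. let-7c-5p per 100 counts of let-7a-5p was 8.09, 9.04 and 10.7 in sensitive and 7.89, 8.38 and 13.3 in resistant libraries, and miR-125b-2-3p, made only from chromosome 21, fell without resistant replicate 3 (log2 fold change -2.70, edgeR adjusted p = 0.00657). A change of the whole chromosome cannot be told apart from 1 at this locus, since 0 other uniquely placed miRNAs on chromosome 21 were tested. miR-548x-3p, which fell, has 1 of its 2 hairpins on chromosome 21, outside MIR99AHG, but its reads may come from the other hairpin, on chromosome 13. Lower activity of the host gene in resistant cells stays open and was not tested.

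miR-181a-3p and miR-181b-3p had 0 counts in the 3 resistant libraries. miR-181a-2-3p, made only from the second copy on chromosome 9, did not pass (log2 fold change 0.55, edgeR adjusted p = 0.365) and lay at least 10.5 above miR-181a-3p on the log2 scale, which argues against a change shared by both copies. The other 50 uniquely placed miRNAs on chromosome 1 had a median log2 fold change of -0.049 (lowest -3.14), which argues against a change of the whole chromosome. What changed at this locus stays open, and DNA copy number and promoter methylation of MIR181A1HG were not analysed here.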
